A study of Homo sapiens with 12 samples.

How the data were processed

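RNA was extracted with Trizol from cells grown in medium without phenol red and treated for 3 h with 10 nM oestradiol or ethanol vehicle, and standard Illumina libraries were made, per the labels. The 12 libraries form 6 groups of 2, from 3 lines and 2 treatments. Whether the 2 libraries of a group came from separate cultures, and whether the replicate numbers mark days or batches, is not stated, so the p-values measure the spread between these samples.

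The authors list STAR 2.4.1c, SAMtools, bedtools 2.17.0, edgeR and R 3.1.1 and the genome build hg38, without saying which step each tool did. The deposited table holds a normalised signal for 51216 RefSeq transcript rows of 24762 genes. In each library the non-zero values were whole multiples of 1 step (100% of them within 0.1 of a read), and the column totals fit edgeR scaling of read counts by TMM effective library sizes, with implied factors whose product is 1. Whole reads were therefore recovered by dividing each column by its step. The recovered reads ranged from 31729569 to 57423468 per library, and 1 read was worth between 0.020159 and 0.0282. The isoform rows of a gene share reads, so that rows of 1 gene are not independent, and up to 33 rows of 1 gene were tested. Strand and the treatment of reads that map to several places are not stated. Values and floors cover counting error only.

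Symbols were blank for 1114 rows, which held between 1.608% and 2.153% of the reads, and 1092 of these were named from their accession. Symbols that read as numbers, as a date conversion leaves them, were kept and not named. RefSeq gene annotation gave a biotype for 51037 rows. GENCODE 29 gave coordinates on GRCh38 for 48912 and a length for 50358.

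The test fixed before the data were examined was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2 of the value plus 1. It used rows with a value of 1 or more in at least 2 libraries (36212 rows of 15348 genes), the 12 libraries in 1 fit with 6 group means and no block (6 residual degrees of freedom), and Benjamini-Hochberg adjustment over the rows of each contrast, two-sided, at 0.05. A gene was counted when any of its rows passed, and the gene lists used 1 row per gene. The contrasts were oestradiol minus vehicle in each line, the 3 differences of these responses, and the vehicle level of the mean of the endometrial lines minus MCF7.

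The fit with the replicate number of each line as a block pairs a vehicle and an oestradiol library, and was planned beside the main test. It has 3 residual degrees of freedom (10.8 prior degrees of freedom, against 2.48 without the block). Whether the numbers pair the libraries was checked from the correlation, across rows, of the replicate 1 minus replicate 2 differences of the vehicle and the oestradiol libraries of a line. It was 0.949 in Ishikawa, 0.578 in JHUEM14 and 0.952 in MCF7. The paired fit leaves each log2 fold change as it is and changes its error and p, and its counts lead the results because the unpaired spread held the replicate difference.

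Both fits were tested on simulated data with the replicate structure of these libraries and 200 changed rows per line at 1.5-fold, 2-fold or 4-fold. The paired limma fit recovered 44.8% to 52.2% of rows changed 1.5-fold, 89.6% to 92.5% of those changed 2-fold and 98.5% to 100% of those changed 4-fold, with 3 to 8 unchanged rows called per line. The unpaired limma fit recovered 0 of the changed rows. Paired edgeR recovered 94% to 95.5% and paired DESeq2 77.6% to 88.1% of rows changed 2-fold, with 13 to 72 and 1 to 5 unchanged rows called. In these data the rows were independent and the spread was the same in every line. A list of 30 genes shifted by 0.5 was called by camera (adjusted p = 1.79e-60) and 0 of 20 unshifted lists were.

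The rule for named genes was also fixed before the data were examined. In each line it takes, among rows past the threshold with both oestradiol libraries on the same side of both vehicle libraries and the higher group mean at least 2, the 10 largest rises and the 10 largest falls, leaving pseudogenes, small RNAs and rows without a symbol unnamed. For the differences it takes the 10 largest past the threshold and of the same sign in both Ishikawa minus MCF7 and JHUEM14 minus MCF7, and the 10 largest of Ishikawa minus JHUEM14. For vehicle levels it takes the 5 largest each way and members of the lists of receptors and cofactors, luminal and Mullerian markers. ESR1, GREB1, PGR, TFF1, MYC and CCND1 and up to 4 members of each list described were added. The rule was applied to the paired calls, because the unpaired fit called none in the endometrial lines. Genes named because they were shared between lines, because they were the 1 member of a list that went the other way, or as the genes of a count of 5 or fewer were chosen after their values were seen.

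The 24 gene lists were also written before the data were examined. They are classical oestrogen-induced and oestrogen-repressed genes of breast cells, uterine and endometrial oestrogen-response genes, oestrogen receptors and cofactors, luminal breast markers, Mullerian and endometrial markers, ribosome biogenesis genes and MYC targets, immediate-early genes, G1 and S phase genes, G2 and M phase genes, replication-dependent histone genes, apoptosis regulators, EGF family ligands and receptors, TGF-beta response genes, retinoic acid pathway genes, glucocorticoid-response genes, aryl hydrocarbon receptor genes, unfolded protein response genes, hypoxia-response genes, interferon-response genes, cholesterol synthesis genes, cytosolic ribosomal protein genes, mitochondrially encoded genes, and stromal, endothelial and immune markers. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a contrast. List values of the responses and of their differences are from the paired fit unless stated otherwise. The counts of list members that differed under vehicle are from the planned fit without the block. The 2 lists of breast oestrogen targets come from textbook knowledge that rests largely on MCF7 cells. A response of those lists in MCF7, or a difference of another line from it, is therefore not independent of how they were made.

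Overlaps used Fisher's exact test per direction over the genes tested. The count of genes past both differences from MCF7 was set beside the product of the 2 counts and beside 20 simulations without an effect, since both differences use the MCF7 libraries. The other settings planned were other pseudocounts, filters, scalings and variance models, the libraries of the lines compared alone, the replicate block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. The settings that join the replicate block with another choice, 1 row per gene and a correction for GC content and length were added after the data were seen. Groups of 2 are too small for counts of other splits of the samples or for a test of outlying samples. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.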

Results

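RNA was sequenced from 3 human cancer cell lines after 3 h with 10 nM oestradiol or with vehicle (ethanol). Ishikawa and JHUEM14 derive from endometrial carcinomas and MCF7 from a breast carcinoma. Oestradiol, the main oestrogen, acts through receptors that bind DNA, of which oestrogen receptor alpha (ESR1) is the best known. Each of the 6 groups of line and treatment had 2 libraries, numbered 1 and 2, which makes 12 libraries in all. The recovered reads ranged from 31729569 to 57423468 per library, and 1 read was worth between 0.020159 and 0.0282 of the deposited normalised signal. The question of the series is how the oestrogen-responsive genes of endometrial and breast cancer lines compare. The libraries of a line with the same number are called a pair here. A gene "rose" or "fell" when at least 1 of its RefSeq rows passed the paired limma test at an adjusted p below 0.05, over 36212 rows of 15348 genes. Log2 fold changes are of the normalised value plus 1, so they understate the ratio of values for genes near 0, and the values of each pair are given as vehicle to oestradiol.

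In MCF7, 869 genes rose and 504 fell, 1373 in all. Of the genes that rose, 107 did so at least 2-fold, and of those that fell, 13. The progesterone receptor gene PGR (NM_000926, GRCh38 chromosome 11, 101029624 to 101130524), a classical target of the oestrogen receptor, rose by a log2 fold change of 2.55 (SE 0.120, adjusted p = 1.44e-08), from 5.52 to 35.0 in pair 1 and from 13.1 to 86.3 in pair 2. The chemokine gene CXCL12 (NM_000609, chromosome 10, 44370165 to 44386493) rose by 2.33 (SE 0.0909, adjusted p = 2.78e-09), from 1.97 to 14.2 and from 3.56 to 21.5. MYC, a transcription factor gene of cell growth (chromosome 8, 127735434 to 127741434), rose by 1.56 (SE 0.139), from 21.2 to 84.8 and from 30.6 to 70.2. GREB1, a cofactor of the oestrogen receptor, rose by 1.304 (SE 0.174), from 71.7 to 155 and from 160 to 458, and the cyclin gene CCND1 rose by 0.66 (SE 0.0995).

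The other largest rises in MCF7 were SMTNL2 (2.62), the tyrosine kinase gene HCK (2.20), the long non-coding RNA LINC01016 (2.174), USP31 (2.08), MYBL1 (2.07), the kinase gene SGK1 (1.995), RAPGEFL1 (1.99) and OSGIN1 (1.98). The largest falls were TNFRSF11B, which encodes osteoprotegerin (-1.42), the WNT pathway inhibitor RNF43 (-1.38), ANKRD33B (-1.36), the growth factor gene TGFB2 (-1.26), GRHL3 (-1.24), the potassium channel genes KCNJ3 (-1.24) and KCNJ8 (-1.20), ARID5B (-1.11), the lactate receptor gene HCAR1 (-1.10) and the cell cycle inhibitor gene CDKN2B (-1.10). ESR1 did not pass the test, with a log2 fold change of -0.18 (adjusted p = 0.319). TFF1, a secreted protein gene used as a marker of oestrogen action, went from 600 to 704 in pair 1 and from 174 to 228 in pair 2 and did not pass either (log2 fold change 0.31, SE 0.141, adjusted p = 0.249).

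Of the 47 tested members of the list of classical oestrogen-induced genes of breast cells, 41 rose in MCF7 and 1 fell, with a median log2 fold change of 1.02. Adjusted over the list alone, 44 rose and 1 fell. PGR, CXCL12, MYBL1 and SGK1 rose most, and CYP1B1, which encodes an oestrogen-metabolising enzyme, fell by 0.47. The list lay above other genes (camera, adjusted p = 1.38e-53, and adjusted p = 0.00796 with an estimated correlation). Of the 24 oestrogen-repressed genes, 14 fell and 1, IRS2, rose (16 and 1 adjusted over the list alone), with a median of -0.497. TGFB2, LIPH (-0.9998) and SMAD6 (-0.93) fell most. The camera test called this list lower at an adjusted p of 1e-16. With an estimated correlation the adjusted p was 0.179 with the pairs and 0.000807 without them, and fry gave an adjusted p of 0.0124 and of 0.00035. Of the 30 genes of ribosome biogenesis and MYC targets, 20 rose and 0 fell (26 and 0 adjusted over the list alone), with a median of 0.551, and PPRC1 (1.04), NIP7 (1.01), NOP16 (1.01) and POLR1B (1.001) rose most. That list had a camera adjusted p of 2.32e-21, and an adjusted p of 0.0769 with an estimated correlation, or 0.0405 without the pairs. Among 30 genes of the G1 and S phases, 4 rose (MYBL1, CCNE1, CCND1 and CDC25A; 4 adjusted over the list alone), and of 24 genes of the G2 and M phases none rose or fell.

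In the planned limma fit without the pairs, 17 genes rose and 1 fell in MCF7, 18 in all. Without the pairs edgeR called 0 and DESeq2 104, and with the pairs edgeR called 1535 genes and DESeq2 770. The paired count was 320 without MCF7 pair 1, 224 without MCF7 pair 2 and 903 without either JHUEM14 pair, where a lone pair is taken to vary like the other lines. Among the MCF7 genes above, CDKN2B lost its call without pair 1, GREB1 without pair 2, CCND1 without either pair and CXCL12 in paired DESeq2.

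**Figure D1:**
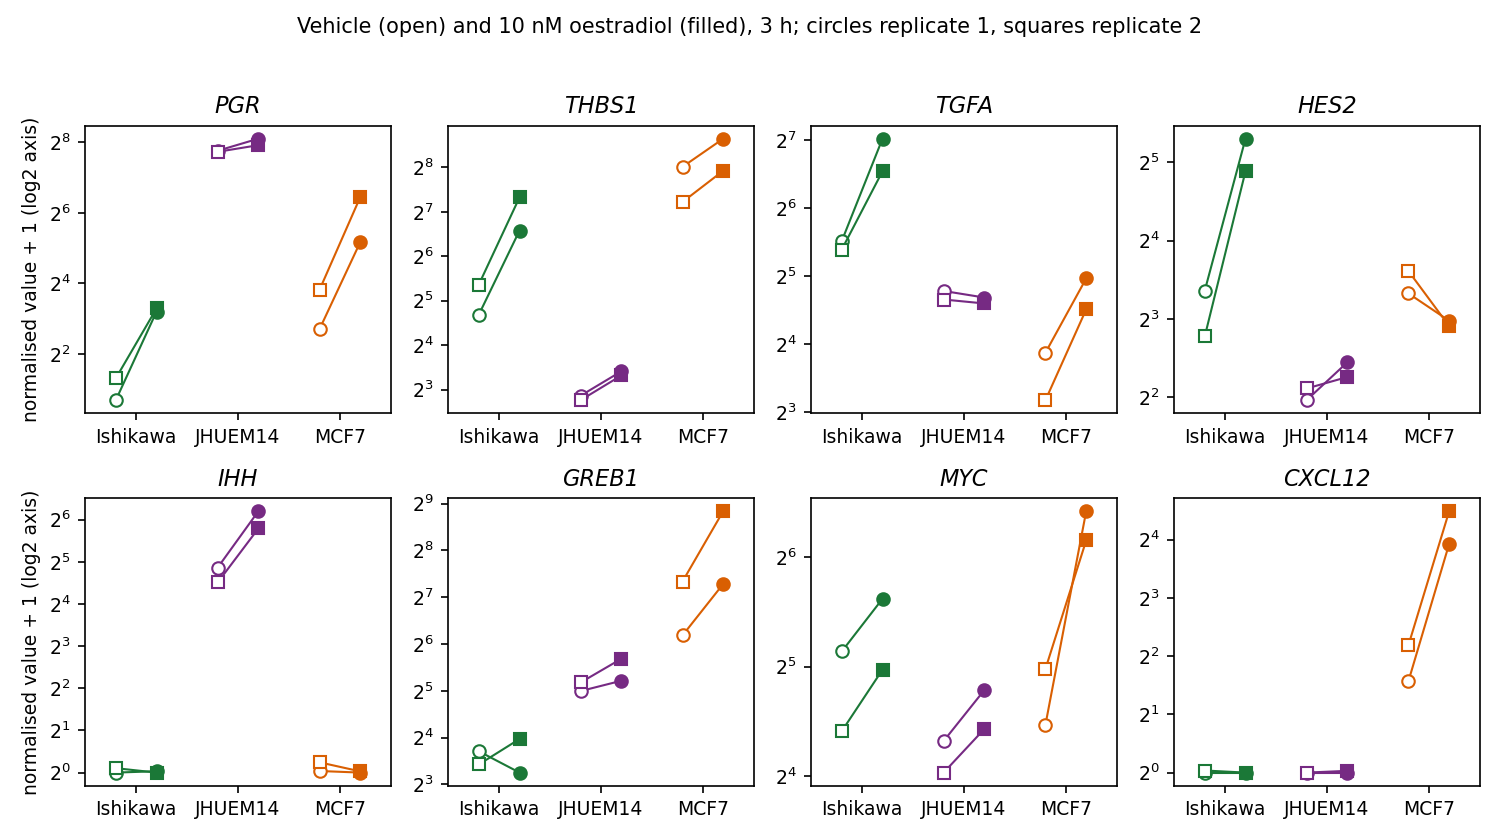
Normalised value plus 1 (log2 axis) of 8 genes in the vehicle libraries (open symbols) and the oestradiol libraries (filled symbols) of Ishikawa, JHUEM14 and MCF7, with circles for replicate 1, squares for replicate 2 and a line for each pair. PGR goes from 0.617 to 8.22 and from 1.48 to 8.81 in Ishikawa, and IHH from 28.1 to 72.7 and from 21.8 to 54.5 in JHUEM14, while CXCL12 stays near 0 in both endometrial lines.

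In Ishikawa, 46 genes rose and 8 fell, 54 in all, and 13 of those that rose did so at least 2-fold. PGR rose most, by 2.25 (SE 0.120, adjusted p = 2.51e-07), from 0.617 to 8.22 in pair 1 and from 1.48 to 8.81 in pair 2. The transcription factor gene HES2 rose by 2.02 (SE 0.128, adjusted p = 1.18e-06), from 9.29 to 38.5 and from 5.86 to 28.6. THBS1 (NM_003246, chromosome 15, 39581079 to 39599466), which encodes the matrix protein thrombospondin, rose by 1.93 (SE 0.0892, adjusted p = 1.68e-07), from 24.7 to 94.7 and from 40.1 to 160. TGFA (chromosome 2, 70447280 to 70554193), a ligand of the EGF receptor, rose by 1.33 (SE 0.108), from 44.8 to 129 and from 41.0 to 92.2. Other large rises were the retinal reductase gene DHRS3 (1.63), the mTOR inhibitor gene DEPTOR (1.48), TSKU (1.34), the placental alkaline phosphatase gene ALPP (1.19), CABLES1 (1.15) and the kinase gene PIM1 (1.06). ALPPL2, whose sequence is close to that of ALPP, rose by 0.95, and reads shared by the 2 genes would enter both values. Of the genes that fell, 2 met the rule for named genes, ARID5B (-0.61, adjusted p = 0.0147) and ANGPTL1 (-0.47, adjusted p = 0.0487).

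MYC went from 34.2 to 48.2 and from 20.2 to 30.4 in Ishikawa (log2 fold change 0.52, SE 0.139, adjusted p = 0.191), and CCND1 from 141 to 163 and from 90.7 to 128 (0.34, adjusted p = 0.238). Paired edgeR called the rise of MYC. GREB1 went from 12.1 to 8.52 in pair 1 and from 9.73 to 14.7 in pair 2, opposite directions, with a log2 fold change of 0.04. ESR1 (log2 fold change -0.14) and TFF1 (0.27, with all 4 values below 1) did not pass the test.

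Among the 47 classical oestrogen-induced genes, 3 rose in Ishikawa, PGR, the receptor corepressor NRIP1 (1.02) and the DNA repair gene RBBP8 (0.87), and none fell. Adjusted over the list alone, 6 rose. The list's median was 0.104 (camera adjusted p = 2.55e-05, and with an estimated correlation adjusted p = 0.185 with the pairs and 0.0178 without them). Of 24 uterine and endometrial oestrogen-response genes, 4 rose (PGR, TGFA, ALPP and ALPPL2; 5 rose and 1 fell adjusted over the list alone), at a camera adjusted p of 0.00866 and, with an estimated correlation, an adjusted p of 0.329 with the pairs and of 0.0347 without them. Of 24 oestrogen-repressed genes, 1 fell, the signalling inhibitor SMAD6 (-0.75), with a median of -0.187, and 2 fell adjusted over the list alone. Its camera adjusted p of 6.18e-06 became 0.405 with an estimated correlation with the pairs, and was 0.0178 there without them. In Ishikawa fry passed none of these 3 lists, with adjusted p values of 0.0886, 0.11 and 0.0886 without the pairs and of 0.0935, 0.0524 and 0.165 with them. The median of the 30 ribosome biogenesis genes and MYC targets was 0.237, of which RRS1 rose (0.67), and 9 rose adjusted over the list alone. The camera adjusted p of that list was 2.53e-11, and the adjusted p was 0.185 with an estimated correlation.

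The planned limma fit without the pairs called 0 genes in Ishikawa, where 95 genes had an unadjusted p below 0.05. Without the pairs, edgeR also called 0 and DESeq2 8, and with the pairs edgeR called 155 and DESeq2 57. The spread behind the paired count was pooled over the lines, and with the Ishikawa libraries alone 3 genes passed, all of them higher. Most calls were rises with every pair kept, but without Ishikawa pair 2 the paired count was 960, of which 391 rose and 569 fell. The count was 32 without Ishikawa pair 1, and between 14 and 16 without any single pair of another line. ARID5B and ANGPTL1 lost their calls without Ishikawa pair 1 and without any pair of another line. The log2 fold changes of the 2 Ishikawa pairs correlated at 0.0962 across rows, against 0.236 in JHUEM14 and 0.722 in MCF7.

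In JHUEM14, 16 genes rose and 10 fell, 26 in all, and 2 rose at least 2-fold. IHH (NM_002181, chromosome 2, 219054420 to 219060467), which encodes the secreted signal Indian hedgehog, rose by 1.31 (SE 0.108, adjusted p = 0.000351), from 28.1 to 72.7 in pair 1 and from 21.8 to 54.5 in pair 2. SPATA13 rose by 0.94 (SE 0.109), from 9.83 to 19.2 and from 11.8 to 24.3. Other rises were G0S2, an inhibitor of fat breakdown (0.89), the long non-coding RNA LINC01101 (0.87), the pluripotency factor gene POU5F1 (0.77), which has pseudogenes, INHBB, an activin subunit (0.71), the transcription factor gene EGR3 (0.68), the coactivator genes PPARGC1B (0.68) and PPRC1 (0.62), and THBS1 (0.55). Of the genes that fell, 8 met the rule for named genes. They were the matrix protease gene ADAMTS5 (-0.77), GCNT1 (-0.72), GPRIN3 (-0.69), the clock output gene DBP (-0.67), TGFB2 (-0.66), ZNF436-AS1 (-0.65), the lipase gene LIPG (-0.56) and PLEKHG7 (-0.52). ZNF436-AS1 is annotated as antisense to another gene, and the files do not say whether reads were assigned by strand.

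PGR went from 216 to 274 and from 211 to 241 in JHUEM14 (log2 fold change 0.27, SE 0.120, adjusted p = 0.596). GREB1 (0.36, adjusted p = 0.643), MYC (0.43, adjusted p = 0.365), CCND1 (0.12) and ESR1 (-0.09) did not pass the test, and neither did TFF1, which was listed at 0 in both vehicle libraries. Of the 47 classical oestrogen-induced genes, EGR3 alone rose in JHUEM14, and 7 rose and 1 fell adjusted over the list alone. Paired edgeR also called RARA and STC2 of this list higher. The list's median was 0.068 (camera adjusted p = 0.00166, and adjusted p = 0.27 with an estimated correlation). Of the 24 oestrogen-repressed genes, TGFB2 alone fell, also adjusted over the list alone, with a median of -0.174 (camera adjusted p = 2.3e-05, and adjusted p = 0.448 with an estimated correlation). The median of the 30 ribosome biogenesis genes and MYC targets was 0.253, of which PPRC1 rose, and 9 rose adjusted over the list alone. The camera adjusted p of that list was 7.77e-19, and the adjusted p was 0.181 with an estimated correlation. IHH was the only one of 24 uterine and endometrial oestrogen-response genes that rose, also adjusted over the list alone.

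The planned limma fit without the pairs called 0 genes in JHUEM14, where 98 genes had an unadjusted p below 0.05, and so did edgeR and DESeq2 without the pairs. With the pairs, edgeR called 51 genes and DESeq2 19. With the JHUEM14 libraries alone 0 genes passed in limma, and the paired count was 5 without JHUEM14 pair 1, 0 without JHUEM14 pair 2 and 2 without either MCF7 pair.

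**Figure D2:**
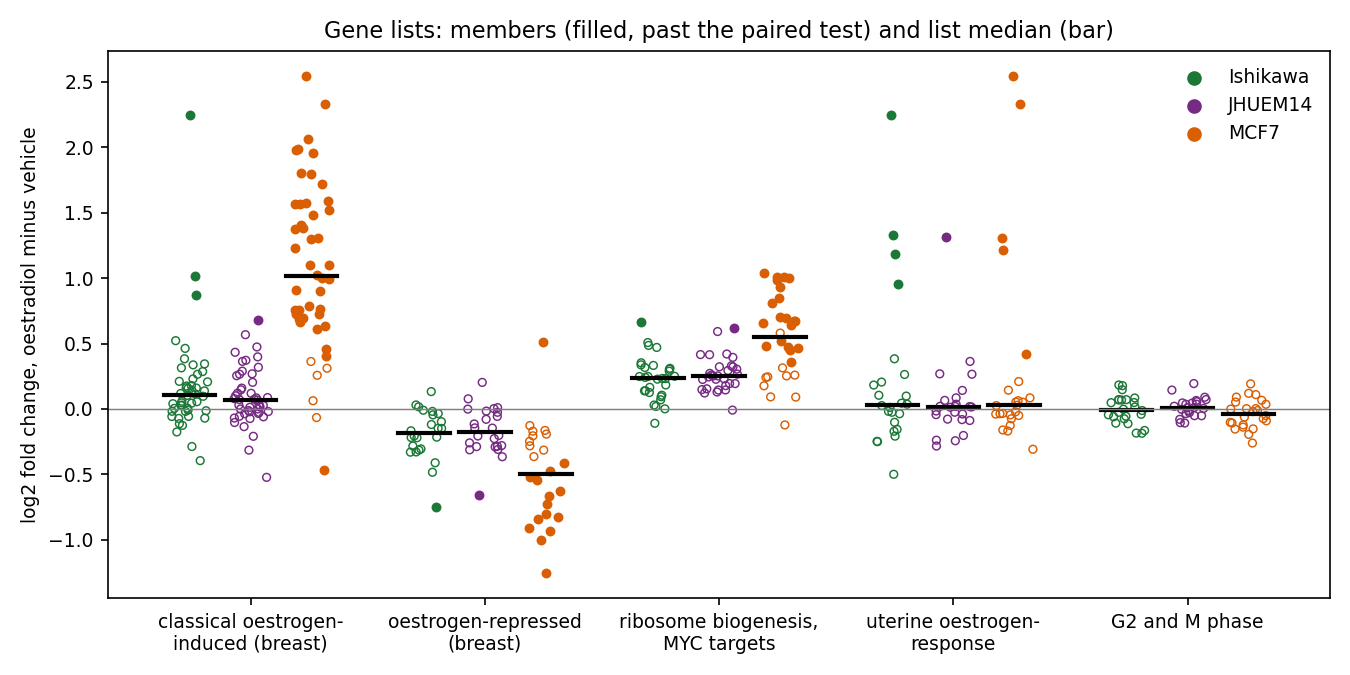
Log2 fold change, oestradiol minus vehicle, of each tested member of 5 gene lists in Ishikawa, JHUEM14 and MCF7, with a filled point for a member past the paired limma test, an open point for the others and a bar at the list's median. The classical oestrogen-induced genes have medians of 0.104, 0.068 and 1.02 in the 3 lines, and the ribosome biogenesis genes 0.237, 0.253 and 0.551.

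The genes that changed overlapped between the lines more than independent lists would. Ishikawa and MCF7 shared 18 genes that rose, against 2.6 expected (Fisher's exact test, p = 1.88e-11). They included PGR, TGFA, THBS1, NRIP1, DEPTOR, PIM1, TSKU and RRS1. POC1B, GALNT4 and the joint gene POC1B-GALNT4, which can share reads, were each counted among the 18. Another 2 genes rose in Ishikawa and fell in MCF7. ARID5B and SMAD6 fell in both of these lines (0.263 expected, Fisher's exact test, p = 0.0264). JHUEM14 and MCF7 shared 6 genes that rose (EGR3, PPARGC1B, PPRC1, SCNN1G, SPATA13 and THBS1; 0.906 expected, Fisher's exact test, p = 0.000159) and 4 that fell (DBP, GCNT1, GPRIN3 and TGFB2; 0.328 expected, p = 0.000206). Ishikawa and JHUEM14 shared 3 genes that rose, G0S2, PPARGC1B and THBS1 (0.048 expected, Fisher's exact test, p = 1.37e-05), and 0 that fell (0.00521 expected). PPARGC1B and THBS1 thus rose in all 3 lines. The paired fit gives each row 1 spread for all 3 lines, so a row with a low spread can pass in several. Fisher's exact test does not allow for this. With each line fitted to its own libraries, the paired overlaps were 2 for Ishikawa and MCF7 and 0 for the others. Without the pairs, limma with the planned filter and edgeR called 0 genes in each endometrial line, so they gave no overlap, and DESeq2 gave 2 genes shared by Ishikawa and MCF7, both higher, and 0 for the other overlaps. Leaving out a pair gave 3 to 148 shared genes for Ishikawa and MCF7 (without MCF7 pair 2 and without Ishikawa pair 2). It gave 0 to 14 for JHUEM14 and MCF7 and 0 to 7 for the endometrial lines, with 0 in both when any pair of JHUEM14 or MCF7 was left out.

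Across the 15348 genes, which are not independent replicates, the log2 fold changes of Ishikawa and MCF7 correlated at 0.259 (Spearman 0.253), those of JHUEM14 and MCF7 at 0.227 (Spearman 0.217) and those of the endometrial lines at 0.115 (Spearman 0.111). Noise lowers such correlations, and the 2 pairs of a line correlated across rows at 0.0962 in Ishikawa, 0.236 in JHUEM14 and 0.722 in MCF7. The correlations between lines therefore do not rank how alike the responses were. The 851 genes whose row with the highest mean rose in MCF7 had a median log2 fold change of 0.548 there, of 0.0954 in Ishikawa and of 0.070 in JHUEM14. Of these genes, 591 (69.4%) had a positive log2 fold change in Ishikawa and 589 (69.2%) in JHUEM14. For the 478 genes that fell in MCF7, the medians were -0.477, -0.0759 and -0.0538, and 341 (71.3%) and 314 (65.7%) had a negative value. Taken from the endometrial side, 35 of 46 genes that rose in Ishikawa had a positive value in MCF7 (median 0.243, against 0.843 in Ishikawa). Of 7 that fell in Ishikawa, 2 had a negative one in MCF7 (28.6%, median 0.03, against -0.52). Of 16 genes that rose in JHUEM14, 9 had a positive value in MCF7 (56.2%, median 0.0153, against 0.686 in JHUEM14). Of 10 that fell in JHUEM14, 7 had a negative one in MCF7 (median -0.04, against -0.662). In each case the genes were selected by their values in 1 line, so a smaller median in another line follows in part from that selection.

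The difference between the responses was tested as an interaction of line and treatment. In the paired fit, 371 genes responded differently in Ishikawa and MCF7 and 433 in JHUEM14 and MCF7. In 203 genes MCF7 had the higher response in both tests, and in 57 the lower. CXCL12 had a difference of -2.35 (SE 0.129, adjusted p = 3.77e-07) for Ishikawa minus MCF7 and of -2.32 for JHUEM14 minus MCF7. SMTNL2 (-2.45 and -2.48), HCK (-2.16 and -2.30), SGK1 (-2.17 and -1.99), LINC01016 (-2.08 and -2.08), OSGIN1 (-2.14 and -1.99), NAV2 (-2.31 and -1.81), MYBL1 (-1.89 and -1.98), RAPGEFL1 (-1.90 and -1.88) and the nuclear receptor gene NR5A2 (-1.60 and -2.15) followed. The response of LINC01016 in the endometrial lines was read from values near 0, and the sign of its difference turned positive in edgeR with the pairs for both lines (1.467 and 1.46) and in DESeq2 for Ishikawa (0.5917).

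Of the 47 classical oestrogen-induced genes, 29 had a lower response in Ishikawa than in MCF7 and 1, RBBP8, a higher one, with a median difference of -0.957 (40 and 2 adjusted over the list alone). In JHUEM14, 31 had a lower response than in MCF7 and 1, CYP1B1, a higher one, with a median of -0.94 (42 and 1 adjusted over the list alone). Both list differences passed camera (adjusted p = 7.77e-42 and 1.1e-49) and kept an adjusted p of 0.0116 and 0.00892 with an estimated correlation. The list rests largely on knowledge of MCF7 cells, so a lower response in another line is not independent of how it was made. Its median log2 level under vehicle was 1.726 and 2.201 in Ishikawa, 2.548 and 2.379 in JHUEM14 and 3.921 and 4.035 in MCF7. Of the 47 members, 26 were higher in MCF7 under vehicle and 4 in the endometrial lines. Since 1 was added to each value, low levels can make a response look smaller, so part of the difference may come from level. The ribosome biogenesis genes and MYC targets had median differences of -0.329 and -0.331. Their camera adjusted p values of 4.39e-08 and 1.69e-06 became an adjusted p of 0.308 and of 0.43 with an estimated correlation. The oestrogen-repressed genes had median differences of 0.346 and 0.35 (camera adjusted p = 6.06e-08 and 1.69e-08). Of the 24, 2 had a higher and 1 a lower response in Ishikawa than in MCF7, and 4 and 0 in JHUEM14 (11 and 1 in both adjusted over the list alone), and with an estimated correlation the adjusted p was 0.481 and 0.43 with the pairs and 0.00884 and 0.00614 without them.

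The 2 endometrial lines differed in the response of 21 genes, 19 higher in Ishikawa and 2 higher in JHUEM14. PGR (1.98, SE 0.169, adjusted p = 0.000147), DEPTOR (1.76), HES2 (1.71), DHRS3 (1.5), TGFA (1.40), TSKU (1.40), THBS1 (1.38), the potassium channel gene KCNJ5 (1.27) and CABLES1 (1.21) responded more in Ishikawa, and IHH (-1.35, adjusted p = 0.00112) more in JHUEM14. Of the uterine and endometrial oestrogen-response genes, 4 of 24 (PGR, TGFA, ALPP and ALPPL2) responded more in Ishikawa and 1 (IHH) less, and 5 and 1 did so adjusted over the list alone (camera adjusted p = 0.0886).

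Without the pairs, limma called 0 genes for Ishikawa minus MCF7 (244 at an unadjusted p below 0.05), 1 for JHUEM14 minus MCF7, which was NR5A2 (adjusted p = 0.0218), and 0 for Ishikawa minus JHUEM14 (60 at an unadjusted p below 0.05). There edgeR called 0, 0 and 0, and DESeq2 9, 13 and 0. With the pairs, edgeR called 372, 360 and 50 genes and DESeq2 210, 198 and 22. Leaving out a pair gave 74 to 883 genes for Ishikawa minus MCF7 (lowest without MCF7 pair 2 and highest without Ishikawa pair 2), 61 to 591 for JHUEM14 minus MCF7 (without JHUEM14 pair 1 and without Ishikawa pair 2) and 0 to 136 for Ishikawa minus JHUEM14 (without either JHUEM14 pair and without Ishikawa pair 2). Of those 136 genes 44 responded more in Ishikawa and 92 more in JHUEM14, so the balance between the 2 lines turned.

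Under vehicle, 3317 genes were higher in the endometrial lines than in MCF7 and 2910 lower, 6223 in all with 4 that had rows in both directions, in the planned limma fit, and 8602 genes differed with replicate number as a block. These values hold the difference between tissues and all other differences between 3 cell lines, of which 1 was from breast. ESR1 (chromosome 6, 151656691 to 152129619) had a mean of 33.4 (SD 13.2) in Ishikawa, 251 (SD 6.43) in JHUEM14 and 130 (SD 12.1) in MCF7, with 2 libraries in each, so the endometrial lines lay on either side of MCF7 and their mean did not differ from MCF7 by the test (log2 difference -0.51, adjusted p = 0.185 in limma). PGR had means of 1.05 (SD 0.613), 214 (SD 3.20) and 9.32 (SD 5.38). The gap junction gene GJA1 (7.24), LDHB (6.94), PSAT1 (6.23), the growth factor gene MDK (6.20) and the N-cadherin gene CDH2 (5.99) had the largest log2 differences towards the endometrial lines. TFF1 (-8.27), DSCAM-AS1 (-7.82), the GDNF receptor gene GFRA1 (-7.40), KRT81 (-7.37) and EEF1A2 (-7.20) had the largest towards MCF7.

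In the planned limma fit, 11 of the 26 oestrogen receptors and cofactors were higher in MCF7, 3 were higher in the endometrial lines and 12 did not differ by the test. With replicate number as a block these counts were 13, 4 and 9. Their median log2 level was 3.798 and 3.272 in the vehicle libraries of Ishikawa, 4.994 and 5.041 of JHUEM14 and 5.101 and 5.741 of MCF7. FOXA1, a pioneer factor for the receptor in breast cells, averaged 119 (SD 12.6) in MCF7, 6.85 (SD 1.89) in Ishikawa and 0.806 (SD 0.0227) in JHUEM14. GATA3 (-6.74), TFAP2C (-4.32), the coactivator NCOA3 (-4.33), the glucocorticoid receptor gene NR3C1 (-4.51) and GREB1 (-2.43) were higher in MCF7. Of the 16 luminal breast markers 13 were higher in MCF7, among them KRT19 (-5.99), MLPH (-4.89), TFF3 (-4.02) and SPDEF (-3.86), and 1 was lower. Of the 16 Mullerian and endometrial markers 13 were higher in the endometrial lines (14 with the block), among them SOX17 (5.43), WFDC2 (4.07) and EMX2 (3.88), and 0 were lower. The transcription factor gene ETV4 (3.99), a cofactor, was also higher there. PAX8 averaged 149 (SD 84.5) in Ishikawa and 0.0556 in JHUEM14, and FOXA2 averaged 42.1 (SD 4.18) in JHUEM14 and 0.251 in Ishikawa, so those differences each rested on 1 endometrial line. In this comparison the median of all tested rows was 0.177 on the log2 scale with the libraries rescaled to the same total, against 0.0163 as deposited.

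**Figure D3:**
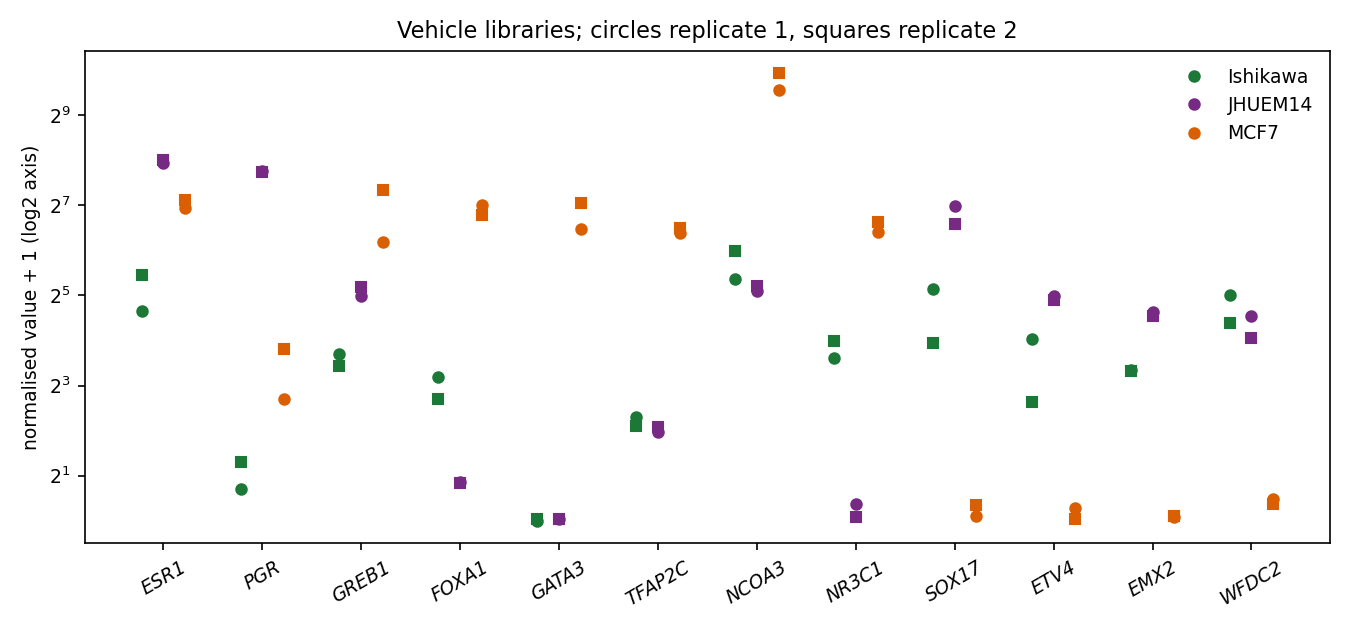
Normalised value plus 1 (log2 axis) of 12 genes in the vehicle libraries of Ishikawa, JHUEM14 and MCF7, with circles for replicate 1 and squares for replicate 2. ESR1 averages 33.4, 251 and 130 in the 3 lines and FOXA1 6.85, 0.806 and 119.

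The numbered replicates differed in every line. Structural RNA genes held between 18.36% and 21.83% of the reads of the replicate 1 libraries and between 5.585% and 12.71% of the replicate 2 libraries. Between the vehicle replicates, 29% of rows differed over 2-fold in Ishikawa, 0.185% in JHUEM14 and 8.49% in MCF7. The nuclear RNA NEAT1 had vehicle values of 23.5 and 393 in replicates 1 and 2 of Ishikawa, 2.109 and 3.102 of JHUEM14 and 351 and 3232 of MCF7. The 22 cytosolic ribosomal protein genes also moved with the replicate number. Their median log2 level was 8.259 and 6.221 in the vehicle replicates of Ishikawa, and with oestradiol 0 of them rose or fell there (1 rose adjusted over the list alone), with a median of 0.151 (camera adjusted p = 6.18e-06, and adjusted p = 0.46 with an estimated correlation).

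The other lists had few members that changed in the endometrial lines in the paired limma fit. Paired edgeR also called MYC higher and RARG lower in Ishikawa and RARA higher in JHUEM14. The counts that follow are from paired limma. Among 26 oestrogen receptors and cofactors, PGR and NRIP1 rose in Ishikawa and none changed in JHUEM14, while PGR, GREB1 and NRIP1 rose and NR3C1, NCOA2 and NCOA3 fell in MCF7. TGFA was the only one of 10 EGF family ligands and receptors that rose in Ishikawa, none changed in JHUEM14, and TGFA and AREG rose in MCF7. DHRS3 was the only one of 13 retinoic acid pathway genes that rose in Ishikawa, none changed in JHUEM14, and CYP26B1, TGM2 and RARA rose and RARG fell in MCF7. EGR3 was the only one of 22 immediate-early genes that rose in JHUEM14, none changed in Ishikawa, and EGR3, MYC, FOS and KLF4 rose and CTGF and BTG2 fell in MCF7. Of 16 unfolded protein response genes, none changed in the endometrial lines, with a median of 0.127 in JHUEM14 (camera adjusted p = 0.00145, and adjusted p = 0.278 with an estimated correlation), and XBP1 and CHAC1 rose and TRIB3 fell in MCF7.

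No member of the following lists rose or fell in Ishikawa or JHUEM14 in the paired limma fit. Paired edgeR called PMAIP1 higher and BMF lower in Ishikawa and STC2 higher in JHUEM14. In MCF7, 4 of 13 glucocorticoid-response genes rose (SGK1, FKBP5, ERRFI1 and GADD45B), 4 of 16 luminal breast markers rose (STC2, XBP1, AGR3 and KRT19), 2 of 16 Mullerian and endometrial markers rose (MEIS1 and STC1), 1 of 17 cholesterol synthesis genes rose (DHCR7), and 1 of 7 tested stromal, endothelial and immune markers rose (VWF). Of 15 apoptosis regulators, PMAIP1 and BCL2 rose and BMF and BIK fell in MCF7, and of 13 hypoxia-response genes, SLC2A1 and VEGFA rose and DDIT4 and EGLN3 fell. None of 17 interferon-response genes, 11 replication-dependent histone genes or 24 G2 and M phase genes rose or fell in any line. The 30 G1 and S phase genes had no member that changed in either endometrial line, and none of the mitochondrially encoded genes had a tested row.

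Adjusted over the list alone, the counts of these further lists were as follows. In Ishikawa 3 receptors and cofactors, 2 luminal markers, 1 immediate-early gene and 1 apoptosis regulator rose, and 1 glucocorticoid-response gene, 1 retinoic acid pathway gene, 1 EGF family gene and 1 apoptosis regulator fell, beside TGFA and DHRS3. In JHUEM14 3 luminal markers, 1 retinoic acid pathway gene, 1 Mullerian marker and EGR3 rose, and 1 Mullerian marker and 1 hypoxia-response gene fell. In MCF7 5 receptors and cofactors, 6 immediate-early genes, 3 unfolded protein response genes and 2 stromal, endothelial and immune markers rose, and 2 retinoic acid pathway genes, 1 glucocorticoid-response gene and 1 stromal, endothelial or immune marker fell, with 0 cholesterol synthesis genes called and the other counts as given above. Some lists passed camera and lost the call with an estimated correlation. They were the luminal markers in Ishikawa (adjusted p = 0.0166, and adjusted p = 0.405 with an estimated correlation) and MCF7 (0.0254, and 0.343), the histone genes, whose median was 0.179 in Ishikawa (0.00181, and 0.913) and -0.128 in JHUEM14 (0.0261, and 0.704), the cytosolic ribosomal protein genes in JHUEM14 (median -0.0744; 0.0261, and 0.676), the interferon-response genes in MCF7 (median -0.186; 0.017, and 0.343), the G1 and S phase genes in MCF7 (0.00325, and 0.348) and the uterine and endometrial oestrogen-response genes in MCF7 (0.0417, and 0.343), of which PGR, CXCL12, GREB1, TGFA and WNT4 rose.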

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

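Of the tests below, the comparison of the covariances, the thinning to equal reads outside structural RNA and the quartiles of the vehicle difference were chosen after the result was seen. The counts past the paired test rest on a fit that was planned beside the main one.

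These results were singled out because the responses of 2 lines differed by a test of the difference itself. In the paired limma fit, 371 genes passed for Ishikawa minus MCF7, 433 for JHUEM14 minus MCF7 and 21 for Ishikawa minus JHUEM14. Past both differences from MCF7 were 203 genes with the higher response in MCF7, against 5.14 for independent counts and at most 1 in 20 simulations without an effect, and 57 with the lower response, against 0.937. Neither reference gives the overlap that the shared MCF7 response alone would leave. The counts are not independent, and simulations without an effect call almost no genes (mean overlap 0.05 per direction). Both differences use the MCF7 libraries, and their correlation across rows was 0.686, against 0.501 in the simulations. The 2 differences were not tested with separate MCF7 pairs, so part of the overlap of 203 and 57 genes may come from the shared libraries.

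The genes with the largest differences from MCF7 were SMTNL2 (-2.454 for Ishikawa minus MCF7 and -2.483 for JHUEM14 minus MCF7), CXCL12 (-2.349 and -2.316), HCK (-2.159 and -2.303), SGK1 (-2.166 and -1.991), LINC01016 (-2.077 and -2.075), OSGIN1 (-2.137 and -1.99), NAV2 (-2.31 and -1.813), MYBL1 (-1.888 and -1.982), RAPGEFL1 (-1.897 and -1.882) and NR5A2 (-1.605 and -2.145). The values of CXCL12 and LINC01016 were near 0 in the endometrial lines, so the difference of CXCL12 largely restates its rise in MCF7. The difference of LINC01016 turned to 1.467 and 1.46 in paired edgeR and, for Ishikawa, to 0.5917 in paired DESeq2. The median difference of the classical oestrogen-induced genes was -0.957 and -0.94, in a list that rests largely on knowledge of MCF7 cells. Its median vehicle level was lower in the endometrial lines than in MCF7, which can make their response look smaller. Between the endometrial lines, Ishikawa minus JHUEM14, the differences were PGR 1.981, DEPTOR 1.762, HES2 1.71, DHRS3 1.5, TGFA 1.404, TSKU 1.398, THBS1 1.377, KCNJ5 1.268, CABLES1 1.209 and IHH -1.348.

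More genes passed the paired test in MCF7 than in either endometrial line (1373 against 54 and 26). With every library thinned to 31729569 reads, in 5 thinnings, MCF7 had a median of 1355 genes, Ishikawa 44 and JHUEM14 15, so MCF7 had 30.8 times the larger endometrial count, and at 29027706 reads outside structural RNA the medians were 1380, 45 and 22, so deeper MCF7 libraries do not account for the count. A spread that is independent between pairs adds nothing on average to the covariance of the log2 fold changes of the 2 pairs, which was 0.0507 in MCF7, 0.00562 in Ishikawa and 0.00774 in JHUEM14, 6.55 times the larger endometrial value (95% interval 5.73 to 7.49 over resampled genes). The paired fit gave each row 1 spread shared by all lines. In these counts a smaller spread in MCF7 would therefore not favour MCF7 over the other lines. The pairs of MCF7 and JHUEM14 disagreed about equally (median over rows 0.12 and 0.134, against 0.199 in Ishikawa). The shared spread may thus be too small for Ishikawa, which would add calls in Ishikawa and not in MCF7. A stronger early response of MCF7 may be the reason, as a hypothesis found and tested on the same data, and tissue is not separable from line with 1 breast line.

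JHUEM14 had the highest vehicle level of ESR1 (251) and of PGR (214) and the fewest genes past the paired test (26 against 54 in Ishikawa), but this order turned with a pseudocount of 4 (64 against 55) and without Ishikawa pair 1 (36 against 32). An exchange of a vehicle and an oestradiol library within a JHUEM14 pair would turn that pair's log2 fold changes against those of MCF7, but over 1329 genes called in MCF7 the correlations were 0.294 in pair 1 and 0.377 in pair 2. The 851 genes that rose in MCF7 were not shifted upward as a set in JHUEM14 over Ishikawa under vehicle. Their median difference was -0.0232, with 0.0264 within replicate 1 and -0.0437 within replicate 2, so its sign depended on the replicate. It lay at percentile 2.28 of matched random lists (37.35 and 0.24 within the replicates, and 76.6 for the 105 genes that rose at least 2-fold), below the bound set before the result. That bound was wrong for genes that go both ways, with quartiles of -0.545 and 0.5 and 409 genes above 0. The quartiles were examined after the result. Whether single genes, such as PGR, were already higher for this reason stays open. A biological difference between the 2 endometrial lines also stays open and was not tested.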

How the results depend on the processing

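The counts of genes past the test in each line and for each difference changed with the processing. The settings planned in advance are given first and those chosen after seeing the data, all with the pairs, after them. The cause of these changes was not tested, except where fewer libraries or the replicate block itself give it. The vehicle count of 6223 stayed within 1.5 times of itself in all its alternatives (4188 to 8602), and using only the lines compared leaves that comparison as it was. Of 160 named values without the pairs, 3982 alternatives gave 3753 on the same side of the threshold, 89 weaker, 122 stronger, 0 turned and 18 with a change of sign in a value that was not called. Of 96 named values with the pairs, 1702 alternatives gave 1385 on the same side, 308 weaker, 4 stronger, 3 turned and 2 with a change of sign in a value not called. Depth limits genes near 0, where 1 read was worth up to 0.0282.

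The planned counts without the pairs were 0 genes in Ishikawa, 0 in JHUEM14, 18 in MCF7, 0 for Ishikawa minus MCF7, 1 for JHUEM14 minus MCF7 and 0 for Ishikawa minus JHUEM14. With the replicate block they were 54, 26, 1373, 371, 433 and 21, the overlaps became 20 (Ishikawa and MCF7), 10 (JHUEM14 and MCF7) and 3 (the endometrial lines), and the lists called became 7, 3 and 3 for the 3 differences, from 4, 6 and 0. Without a filter the counts were 1 in Ishikawa, 45 in MCF7, and 4, 3 and 1 for the differences. DESeq2 gave 8 in Ishikawa, 104 in MCF7, 9 and 13 for the differences from MCF7 and 2 genes shared by Ishikawa and MCF7. The MCF7 count was 9 with a pseudocount of 0.25, 34 with a pseudocount of 4, 11 with a minimum of 5, 10 with the same total, 8 with no trend, and 0 with only the lines compared or edgeR. JHUEM14 minus MCF7 was 0 with a pseudocount of 0.25, the same total, quantile scaling, no trend, only the lines compared and edgeR, and Ishikawa minus MCF7 was 1 with a pseudocount of 4. Leaving out each library gave 3 to 8 genes in MCF7 and 0 to 0 for JHUEM14 minus MCF7.

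Without the block, 5 lists passed camera in Ishikawa, 6 in JHUEM14 and 9 in MCF7. With an estimated correlation 3, 0 and 3 lists passed, and 2 and 2 for the differences from MCF7. With fry 0, 0 and 4 passed, and 2 and 2 for the differences. The replicate block with an estimated correlation left 0, 0 and 1, and 1 and 1 for the differences, and the replicate block with fry 0, 0 and 8, and 1 and 6 for the differences.

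In the paired fit, taking the replicate block away gives the planned counts above (0, 0, 18, 0, 1 and 0) and overlaps of 0, 0 and 0. In the order Ishikawa, JHUEM14, MCF7, the 2 differences from MCF7, the endometrial difference, and the overlaps of Ishikawa and MCF7, of JHUEM14 and MCF7 and of the endometrial lines, the replicate block with no filter gave 18, 1, 905, 141, 139, 6, 4, 0 and 0. In the same order, the replicate block with a correction for GC content and length gave 218, 149, 2261, 733, 816, 87, 105, 67 and 24. Paired and with only the lines compared, the counts were 3 in Ishikawa, 0 in JHUEM14, 182 for Ishikawa minus MCF7, 10 for the endometrial difference, and overlaps of 2, 0 and 0. Paired edgeR gave 155 in Ishikawa, 51 in JHUEM14, 50 for the endometrial difference and overlaps of 55, 22 and 5. It turned the difference of LINC01016 to 1.467 for Ishikawa and 1.46 for JHUEM14 against MCF7, and paired DESeq2 to 0.5917 for Ishikawa. Paired DESeq2 gave 770 in MCF7 and 210 and 198 for the differences from MCF7. The replicate block with a pseudocount of 4 gave 64 in JHUEM14 and overlaps of 16 (JHUEM14 and MCF7) and 1 (endometrial lines). With 1 row per gene it gave 16 in JHUEM14 and overlaps of 6 and 1, with a minimum of 5 it gave 34 for the endometrial difference, and with the same total 1 gene shared by the endometrial lines. Without Ishikawa pair 2, 391 genes rose and 569 fell in Ishikawa, and 44 and 92 were higher and lower for the endometrial difference. Leaving out a pair gave 14 to 960 genes in Ishikawa, 0 to 36 in JHUEM14, 224 to 1851 in MCF7, 74 to 883 for Ishikawa minus MCF7, 61 to 591 for JHUEM14 minus MCF7, 0 to 136 for the endometrial difference, and overlaps of 3 to 148, 0 to 14 and 0 to 7.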

Other observations

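Of the tests below, those of GC content and length and of MCF7 material were chosen after the result was seen, and the test of non-coding RNA was written before.

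Of 13 tested TGF-beta response genes, 5 fell, 1 rose and 7 did not pass the test in MCF7. SMAD6 (-0.93), the differentiation inhibitors ID3 (-0.92), ID1 (-0.85) and ID2 (-0.73), and CTGF (-0.73) fell, and the pathway inhibitor SMAD7 rose (0.50). Adjusted over the list alone, 7 fell and 2 rose, and the camera adjusted p of 0.000531 became an adjusted p of 0.42 with an estimated correlation. ID1 went from 40.4 to 22.6 and from 16.2 to 8.31. In Ishikawa SMAD6 alone fell (-0.75), also adjusted over the list alone, and in JHUEM14 no member of the list rose or fell. The JHUEM14 list had a median of -0.115 and a camera adjusted p of 0.00415, which became an adjusted p of 0.644 with an estimated correlation. TGFB2, the ligand gene, fell in JHUEM14 and in MCF7. The difference of the response was significant in the paired limma fit for ID1, ID2 and ID3 against Ishikawa and for ID1 and ID3 against JHUEM14.

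Genes of the aryl hydrocarbon receptor pathway, which handles dioxin-like compounds, split in MCF7. Of 8 tested members, the receptor's repressor TIPARP (1.74) and the amino acid transporter SLC7A5 (0.996) rose, and the enzyme genes CYP1A1 (-0.91), CYP1B1 (-0.47) and UGT1A6 (-0.31) fell (2 and 4 adjusted over the list alone). SLC7A5 and CYP1B1 are also in the list of classical oestrogen-induced genes, and CYP1A1 is in that of oestrogen-repressed genes. The split is therefore not separate from the results of those lists. TIPARP went from 15.3 to 52.0 and from 18.9 to 67.4, and CYP1A1 from 19.0 to 11.1 and from 40.0 to 18.1. No member rose or fell in Ishikawa or JHUEM14 (1 and 2 rose adjusted over the list alone), though paired edgeR called TIPARP higher in Ishikawa. In JHUEM14 the camera adjusted p was 0.0069, and the adjusted p was 0.278 with an estimated correlation.

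The median of the ribosome biogenesis genes and MYC targets was above 0 in all 3 lines (0.237 in Ishikawa, 0.253 in JHUEM14 and 0.551 in MCF7). In Ishikawa the median log2 level of the list went from 5.05 to 5.389 in pair 1 and from 4.418 to 4.887 in pair 2. In JHUEM14 it went from 4.45 to 4.542 and from 4.331 to 4.604, and in MCF7 from 4.781 to 5.195 and from 4.36 to 4.833. None of the 3 list tests passed with an estimated correlation in the paired fit (adjusted p = 0.185, 0.181 and 0.0769), and without the pairs MCF7 alone did (0.0405).

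Replicate 1 and replicate 2 of a group differed in the same genes in the 3 lines, and the vehicle replicate differences correlated across genes at 0.797 between Ishikawa and MCF7, 0.527 between the endometrial lines and 0.531 between JHUEM14 and MCF7. A bias with GC content and transcript length explained 33.6% of the variance of that difference in Ishikawa, 15.6% in JHUEM14 and 27.4% in MCF7, over 15095 genes, so it is not the whole cause. MCF7 material mixed into an Ishikawa replicate is excluded as the cause, as far as 16 and 17 genes show. These had a value of 100 or more in MCF7 vehicle and lay 100 times lower in the other Ishikawa vehicle replicate, and their median was 0.14% of the MCF7 level in replicate 1 and 0.147% in replicate 2. A larger share of nuclear or unspliced RNA in replicate 2 stays open as a candidate explanation, since the median of 880 long non-coding RNA genes, replicate 1 minus 2, was -0.342 in Ishikawa, -0.0618 in JHUEM14 and -0.177 in MCF7, and in each line it lay at percentile 0 of 10000 lists of coding genes matched by level. These lists were not matched for GC content or length, so the test cannot separate this explanation from the bias above.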
